A study of Homo sapiens with 15 samples.

How the data were processed

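Expanded human ILC2s were cultured alone, with MOLM13 or with U937 cells, and each co-culture was also set up with an antibody against DNAM-1, per the labels. The medium held IL-2 at 500 IU/ml and IL-7 at 20 ng/ml. The protocols also name IL-15 at 20 ng/ml as added to some cultures, but which of the 15 samples received it is not given in the sources used here. ILC2s were sorted, cDNA was made from 2 ng of total RNA with a SMART-Seq v4 low-input kit and sheared, and libraries were sequenced as single reads of 51 cycles on an Illumina HiSeq instrument, per the labels' protocols. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here.

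The 1 processed file is a table of genes with, per the file headers, the symbol, chromosome, start, end, strand, gene model length in kb and description of each gene, followed by 15 columns of values. The deposited gene starts, ends and lengths are properties of the gene, another kind of value than a measurement, and were the only numeric columns used. The 15 per-library columns, deposited as read counts per the name of the processed file, were not used. Their names consist of 1 of 5 letters and a digit, with 3 columns per letter. A search of all sample labels and the series record for these names as separate words found 0 of them. Sample titles instead carry 1 of 3 set numbers and a suffix that follows the culture condition. No key from letters to conditions was at hand, and column order, column totals and gene levels were not used to make one.

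Samples were grouped by their source names, in 5 groups of 3. The tests, gene lists and alternatives for all comparisons had been fixed before the data were examined, with a quasi-likelihood model of counts planned as the main test. None of these tests was run, since none can be made without knowing which library belongs to which group. Totals of the 15 columns can be formed without a key, but they could not be given as the depth of a named sample or group, and they are not reported here.

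Gene rows were described with Python 3.11.15 and pandas 2.3.3. Symbols were matched to GENCODE release 29 gene names, and a symbol was counted as matched when exactly 1 gene of the primary assembly bore that name. Matched genes were checked for the same chromosome and strand with overlap, and for both ends lying within 1 kb. The same counts were made with a RefSeq gene table of GRCh38 and with end tolerances of 0.1 kb and 10 kb. The genes whose positions are given come from the list of genes to be reported in every case, fixed before the data were examined. That rule also asked for the genes with the largest changes in each comparison, which were not determined.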

Results

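RNA sequencing was performed on human group 2 innate lymphoid cells (ILC2s), lymphocytes that lack rearranged antigen receptors and are best known for secreting type 2 cytokines. The cells had been expanded in culture and were sorted by flow cytometry before RNA isolation. The 15 samples fell into 5 groups of 3. ILC2s were kept alone, cultured with MOLM13 cells, or cultured with U937 cells, and each of the co-cultures was also set up with an antibody against DNAM-1. MOLM13 is an acute myeloid leukaemia line and U937 is a line with monocytic features derived from a histiocytic lymphoma. DNAM-1, encoded by CD226, is an activating receptor of lymphocytes that binds CD112 and CD155 on target cells.

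The design implies a comparison of each co-culture with ILC2s alone, of each co-culture with and without the antibody, and of one target line with the other. The question, as far as the labels and the series title give it, is how exposure to tumor cells and blockade of DNAM-1 alter the ILC2 transcriptome, with granzyme B as the effector named in the title. No expression value and no comparison between groups is reported here. The 15 columns of read counts carry names made of a letter and a digit, and none of these names occurs in any sample's labels. The 5 letters with 3 columns each have the same shape as the 5 groups of 3. The search covered whole column names only, and no pairing of a letter with a culture condition was found in the labels or file headers. An assignment by column order would be an unverified guess. An assignment by the level of genes such as GZMB or of leukaemia markers would presuppose the outcome that the comparisons are meant to measure. Without an assignment, no fold change, no error and no depth per group is given.

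The table held 25168 gene rows, each with a different gene symbol. Of these, 23572 symbols (93.7%) matched exactly 1 gene of GENCODE release 29, comprising 18733 protein-coding genes and 4839 genes of other types. The matched rows lay on the same chromosome and strand as the GENCODE gene and overlapped it in 23469 cases (99.6%), and both ends agreed to within 1 kb in 21261 cases (90.2%). The coordinates given here are those of the table. The build behind the table is not given in the sources used here. GENCODE release 29 is on GRCh38, and both ends of 20721 of the 23572 matched rows lay within 0.1 kb of its genes. The positions of those rows are therefore GRCh38 positions. No other build was compared. The gene model length had a median of 3.31 kb against a median genomic span of 21.3 kb, and it exceeded the span in 0 rows.

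The genes central to the design all had a row. GZMB, which encodes the cytotoxic serine protease granzyme B, was placed on chromosome 14 from 24630954 to 24634267 on the minus strand, with a gene model length of 1.40 kb. PRF1, which encodes the pore-forming protein perforin, was placed on chromosome 10 from 70597348 to 70602775 on the minus strand. CD226, the DNAM-1 gene, was placed on chromosome 18 from 69831158 to 69961803 on the minus strand, with a gene model length of 13.6 kb. TIGIT, which encodes an inhibitory receptor for the same ligands, was placed on chromosome 3 from 114276913 to 114310288 on the plus strand. FOXO1, which encodes a forkhead transcription factor of lymphocyte quiescence, was placed on chromosome 13 from 40555667 to 40666597 on the minus strand. Of the ILC2 genes, GATA3, a lineage transcription factor, was placed on chromosome 10 from 8053604 to 8075198, and the type 2 cytokine genes IL5 and IL13 were placed on chromosome 5, from 132541444 to 132556838 and from 132656263 to 132661110.

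The gene lists drawn up for this tissue and treatment were covered almost completely by rows of the table. Of the 324 distinct genes of the 16 program lists, 323 had a row, including all 18 cytotoxic effectors, all 19 FOXO1-associated genes, all 18 ILC2 identity genes and all 8 type 2 cytokines. In the list of type 1 cytokines and chemokines, 20 of 21 genes had a row, and CCL4 had none under this symbol. Of the 87 distinct genes of the 7 cell type lists, 84 had a row, including all 32 markers of myeloid leukaemia cells. Of the 13 T cell markers 10 had a row. The T cell receptor constant genes TRAC, TRBC1 and TRBC2 had no row under these symbols. A row shows that a gene was in the annotation used for counting, not that it was expressed.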

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

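No paired analysis was possible because no column of counts could be matched to a sample or to a group, so the set numbers in the titles could not be used as a block. For the same reason no other normalization, tool, filter on low counts or left-out library was run, and depth was not examined as a limit, since no result rests on it. The alternatives for the gene rows were chosen after seeing the table. With a RefSeq gene table of GRCh38 in place of GENCODE release 29, 23268 rather than 23572 symbols matched exactly 1 gene, and both ends lay within 1 kb for 17104 rather than 21261 rows. With GENCODE release 29, both ends lay within 0.1 kb for 20721 rows and within 10 kb for 22217 rows.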
